A study of Mus with 6 samples.

How the data were processed

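Gene expression was measured by RNA sequencing in 6 mouse libraries labelled as basolateral amygdala, 3 labelled as wild-type (WT) mice and 3 labelled as Cntnap4 knockout mice (KO). Per the labels' protocols, total RNA was purified on silica columns and libraries were made with a SMARTer mRNA kit. Per the submitters' processing notes, the genome build was GRCm38, also written mm10. The aligner, the counting program and the annotation release are not given in the sources used here, and neither is whether counting used strand. The authors deposited 1 table of FPKM values, which are fragments per kilobase of gene scaled to library size. It holds 54532 genes with their symbol, coordinates, biotype and gene length. All sample columns were matched to a sample by name, and 0 columns of sample values were left unmatched.

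The deposited FPKM multiplied by the deposited gene length came out as whole multiples of 1 step per library. With that step as 1 read, 100% of the nonzero values lay within 0.01 of a whole read. The recovered reads in genes numbered 18375949, 17789079 and 20813211 for WT replicates 1 to 3 and 18936386, 18684512 and 17647556 for KO replicates 1 to 3. The library totals implied by the authors' scaling were 0.969 to 1.04 times these sums, so the FPKM scale was not tied exactly to the reads in genes. In a gene of 1 kilobase, 1 read corresponded to 0.0460 to 0.0564 FPKM. Reads carry no molecular identifiers here, so Poisson intervals and limits of 3 reads cover counting error only. Genes with near-identical copies, overlapping genes and antisense genes are uncertain, because the treatment of shared reads is not known.

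The main test was limma-trend with robust empirical Bayes moderation (limma 3.58.1 in R 4.3.3) on log2(FPKM + 0.5). It covered the 16155 genes with a mean of at least 0.5 FPKM over the 6 libraries, of which 13376 were protein-coding. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 changes are KO minus WT on the log2(FPKM + 0.5) scale, which understates the change of low genes, and errors beside them are standard errors. FPKM values are given as mean ± SD with n = 3 per group. The 6 Cntnap4 values also went through an exact two-sided permutation test. The smallest p that 3 against 3 samples allow in such a test is 0.1. Separate mice are named in the labels only by number, so p-values measure the spread between these samples.

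The 35 gene lists were fixed before the data were examined. They covered cell types, brain regions, synaptic and signalling genes and general cell functions, and each had at least 5 tested genes. Each list was tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 35 lists and Cntnap4 left out. The same test with an estimated correlation, and limma's fry rotation test, were alternatives. Counts of list members were adjusted over all genes and over the list alone. Genes within 10 Mb of Cntnap4 were compared with all others by Fisher's exact test, two-sided.

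Named genes followed a rule fixed before the data were examined. It took Cntnap4, then 12 genes in each direction with a mean of at least 1 FPKM and no overlap between the groups, leaving out unnamed gene models. Genes past the adjusted threshold came first by size of change, and the remaining places went to the smallest unadjusted p. It also took up to 4 members with the smallest p in each list that passed and in 6 lists of interest, and called genes within 10 Mb of Cntnap4. From this set the text names the top genes and examples from lists. Other genes were named outside the rule, after their values were seen. They are Slc17a6, Rspo2, Penk, Avp, Oxt, Otp, Chat, Slc18a3, Ngfr, Mbp, Fkbp5, Crh, Wfs1, Dkk3, Ezr, Pmepa1, Kcnj3, Kcnj10, Ttr, Mcam, Itm2a, Il33, Zfp1, Gm44455, Slc13a4, Aldh1a2, the Rps3a family, Xist and the Y-linked genes.

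The alternatives were pseudocounts of 0.1 and 1, no filter, a filter at 5 FPKM, rescaling to an equal FPKM sum per library, median-ratio size factors and quantile normalization. Others were empirical Bayes without trend or robust settings, array quality weights, the replicate number as a block, protein-coding genes only, an adjusted p of 0.1 and a minimum log2 change of 0.58. Windows of 5 and 20 Mb, voom on the recovered reads and leaving out each library in turn completed the planned set. A filter of 10 reads per library and removal of the gene length trend, with a loess span of 0.5, were added after seeing the data, as was voom for Cntnap4 and the lists.

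The gene test was checked on simulated reads for the KO and WT comparison, with 16155 genes and 100 changed at each fold size. It recovered 75% of the 2-fold and 95% of the 4-fold changes with 8 false calls, and made 0 calls when no gene was changed. These shares hold for the simulated spread between libraries and do not give the share of real changes found. In the real comparison 2 genes passed, whereas Cck (log2 1.17, limma adjusted p = 0.184) and Klk6 (log2 -1.30, limma adjusted p = 0.113) did not. The list test found the 1 simulated shifted list and 0 others. Simulated genes were drawn independently of each other. This check therefore could not test how correlation between genes affects the list test. Replicates were compared for duplicates over genes with at least 20 reads in a pair. Chi-square per degree of freedom ranged from 8.82 to 39.0, so no pair agreed within sampling noise and each library counted as 1 sample. Plots were drawn with matplotlib 3.10.9.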

Results

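Gene expression profiles of tissue labelled as basolateral amygdala, a brain region central to fear memory, were compared between 3 samples labelled WT and 3 labelled KO. The comparison asks which transcripts differ between these groups, named for Cntnap4, a neuronal adhesion protein of the neurexin superfamily. The series title also names a bacterial treatment, Lactobacillus reuteri, and no treated sample was analysed here. Libraries held 17647556 to 20813211 reads in genes, and between 25482 and 26319 genes were above 0. Pearson correlations of log2 values across genes were 0.978 to 0.983 within WT, 0.970 to 0.979 within KO and 0.963 to 0.975 between the groups. Mitochondrial transcripts took 6.90%, 8.14% and 3.42% of reads in WT replicates 1 to 3, and 6.19%, 5.63% and 6.28% in KO replicates 1 to 3. Among excitatory neuron genes, WT libraries held Slc17a7 at 5.83 ± 0.535, Slc17a6 at 15.3 ± 1.80, Neurod2 at 0.965 ± 0.350, Neurod6 at 0.579 ± 0.160, Rspo2 at 0.438 ± 0.0751, Nrgn at 228 ± 21.4 and Camk2a at 129 ± 15.3 FPKM. Among genes abundant in striatum, basal forebrain or hypothalamus they held Penk at 383 ± 64.3, Ppp1r1b at 248 ± 31.0, Avp at 609 ± 229 and Chat at 13.2 ± 0.511 FPKM. By mean level over the 6 libraries, Avp ranked 30, Penk 41 and Ppp1r1b 64 of all genes, whereas Slc17a7 ranked 1987. No reference tissue was compared, so the share of each brain region in the pieces was not measured. Differences below are between the pieces as dissected and cannot be assigned to basolateral amygdala alone. These markers were chosen after their values were seen. All 6 samples are labelled male. The library labelled KO replicate 1 nevertheless held Xist, the transcript of the inactive X chromosome, at 43.0 FPKM, against at most 0.0346 FPKM in the other 5. It had 0 reads on the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, where the other 5 libraries had 2831 to 4001.

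Cntnap4 transcripts measured lower in every KO library than in any WT library. The gene (ENSMUSG00000031772, chromosome 8, 112570043 to 112882717, plus strand, GRCm38) measured 2.03, 3.59 and 4.91 FPKM in WT replicates 1 to 3. It measured 1.61, 1.00 and 1.48 FPKM in KO replicates 1 to 3. These values rest on 235, 405 and 670 reads in WT and 190, 114 and 165 reads in KO. KO replicate 1, which has the female transcript Xist, was the KO library nearest to WT, and its 95% Poisson interval (1.39 to 1.85 FPKM) overlaps that of WT replicate 1 (1.78 to 2.30 FPKM), which is no test of their difference. The mean was 3.51 ± 1.44 FPKM in WT and 1.36 ± 0.320 FPKM in KO (SD, n = 3 each), and KO stood at 38.9% of WT. The log2 difference of -1.05 ± 0.28 did not pass the limma test (adjusted p = 0.220). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 samples allow. Which part of the gene was removed is not given in the sources used here, so reads outside that part check the labels only by their level.

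**Figure D1:**
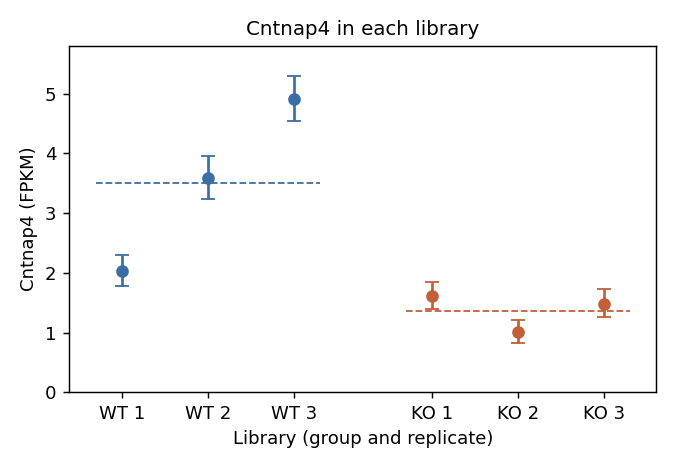
Cntnap4 level in FPKM (vertical axis) in each of the 6 libraries (horizontal axis), with bars for the 95% Poisson interval of the read count and dashed lines for the group means. The 3 KO libraries lie between 1.00 and 1.61 FPKM, below the lowest WT library at 2.03 FPKM.

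Of 16155 genes, 2 passed the adjusted threshold, and both are short RNAs with few reads. Scarna17, a small Cajal body RNA on chromosome 18 (74778391 to 74778469), was higher in KO at log2 1.69 ± 0.14, limma adjusted p = 0.0470. It had 1 read in each WT library and 4, 5 and 5 reads in KO. Gm44455, a microRNA model on chromosome 2 (38225041 to 38225122), was lower, with 2, 2 and 3 reads in WT and 0 in each KO library. Gm44455 falls outside the naming rule and was chosen after its values were seen. Each call was lost without WT replicate 1, 2 or 3 or KO replicate 3 (0 genes passed) and without KO replicate 2 (1 passed, Slc17a7). A filter of at least 10 reads per library left both genes out of the test, and 0 genes passed. Without KO replicate 1, 9 genes passed, Scarna17 among them and Gm44455 not. The 9 also included Mir8099-2, Hist1h2al and Mir874, with means of 3.83, 8.17 and 1.67 reads over the 6 libraries. Rps3a2, Rps3a3 and Gm6166, copies of a ribosomal protein gene with uncertain values, were among them as well. Cck and Cckbr made up the rest. An unadjusted p under 0.05 was reached by 2457 genes, 1351 higher and 1106 lower in KO, against 808 that chance would give. The 3 WT and 3 KO values did not overlap for 22.6% of genes, where chance gives 10%.

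The following genes had the smallest unadjusted p and missed the adjusted threshold. The inhibitory neuropeptide Npy (chromosome 6, 49822710 to 49829507) measured 46.3 ± 3.93 FPKM in WT and 89.6 ± 8.22 in KO, log2 0.94 ± 0.10, adjusted p = 0.104. Cck, the cholecystokinin precursor, measured 22.1 ± 0.433 and 51.6 ± 12.6 FPKM, log2 1.17 ± 0.18, adjusted p = 0.184. Nrgn, which encodes the postsynaptic calmodulin-binding protein neurogranin, measured 228 ± 21.4 and 418 ± 52.4 FPKM. Positive log2 differences also came from Brms1 (0.57), Frg1 (0.48), Rerg (0.59), Ido1 (0.88), Gar1 (0.47), Plvap (0.59), Hspa2 (0.66) and Mir6955 (1.18). On the lower side, the protease gene Klk6 (chromosome 7, 43824499 to 43832030) measured 5.04 ± 1.06 FPKM in WT and 1.72 ± 0.0369 in KO, log2 -1.30 ± 0.14, adjusted p = 0.113. Opalin, a myelin protein gene, measured 24.6 ± 3.45 and 11.5 ± 2.76 FPKM, and Slc5a7, the high-affinity choline transporter, 17.8 ± 1.86 and 10.6 ± 1.20 FPKM. Negative log2 differences also came from Plekhh1 (-0.63), Sytl5 (-1.02), Trim59 (-0.71), Cdc42ep2 (-0.64), Capza1 (-0.66), Hipk2 (-0.54), Enpp2 (-0.79) and Mir7655 (-2.48). Mir7655 averaged 3 reads per library in WT and 0 in KO, below any reliable fold. Rescaling to an equal FPKM sum per library gave 8 genes and brought Klk6 (log2 -1.51, adjusted p = 0.0405) and Sytl5 (-1.19, adjusted p = 0.0405) past the threshold.

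Of the 35 gene lists, 18 passed the list test at the preset correlation, 12 higher and 6 lower in KO. With an estimated correlation 0 lists passed, and fry called 0, with a lowest adjusted p of 0.247. No member of any list passed over all genes, so the count over all genes was 0 for each list below.

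Markers of excitatory neurons were higher in KO as a list, and their level differed among KO libraries. The 26 tested genes had a median log2 difference of 0.54, with 9 higher and 0 lower when adjusted over the list alone. The list had an adjusted p of 1.92e-06 in camera, and adjusted p = 0.574 with an estimated correlation. Slc17a7, the vesicular glutamate transporter VGLUT1, measured 5.69, 5.37 and 6.42 FPKM in WT replicates 1 to 3 and 21.4, 94.3 and 19.1 FPKM in KO replicates 1 to 3. Without KO replicate 2 it was the only gene that passed over all genes, at log2 1.71, adjusted p = 0.0210. The transcription factor genes Neurod6 (log2 1.89 ± 0.36) and Neurod2 (1.90 ± 0.45) were among the 9, as was Nrgn. Without KO replicate 2 the list median was 0.32. Transcripts of hypothalamic neurons were lowest in that same library. Avp measured 783, 695 and 350 FPKM in WT and 894, 2.20 and 325 FPKM in KO replicates 1 to 3, and Oxt 167, 209 and 133 against 168, 0.103 and 12.5 FPKM. The 25 genes of thalamus, hypothalamus and habenula had a median of -0.22 and 0 members adjusted over the list alone (camera adjusted p = 0.0339, adjusted p = 0.702 with an estimated correlation). Zic1 (-0.48) and Slitrk6 (-0.50) had the smallest p there. That call was lost without KO replicate 2 (median -0.06), WT replicate 2 (-0.19) or WT replicate 3 (-0.26), and the median was -0.34 without KO replicate 1 and -0.38 without KO replicate 3. It was also lost with no filter, rescaling to an equal sum, quantile normalization, array quality weights or the length trend removed, with medians from -0.17 to -0.31. Among genes of at least 5 FPKM it held with a median of -0.59.

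Genes of dopamine signalling and medium spiny neurons, the projection neurons of striatum, had a median log2 difference of 0.39 over 27 genes (camera adjusted p = 8.01e-07, adjusted p = 0.574 with an estimated correlation). Adjusted over the list alone 1 was higher and 0 lower, Ido1. The list mixes markers of medium spiny neurons with dopamine synthesis genes, and the latter did not follow the median. Th measured 5.25 ± 0.257 FPKM in WT and 3.32 ± 1.35 in KO (log2 -0.65), and Ddc had a log2 difference of 0.04. Among the dopamine receptor genes, Drd1 (0.47) and Drd2 (0.50) were higher and Drd3 (-0.41) lower. Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, measured 248 ± 31.0 FPKM in WT and 398 ± 81.7 in KO, rank 64 of all genes by mean level. In KO replicate 2, singled out after its values were seen, these genes lay a median log2 of 0.51 above the mean of KO replicates 1 and 3. The middle 95% of random lists matched on level spans -0.11 to 0.09. Random lists lack the correlation between genes of a cell-type list, so this range is too narrow to serve as a test. The KO minus WT median of the dopamine and medium spiny list was 0.29 without KO replicate 2 and 0.63 without KO replicate 3.

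**Figure D2:**
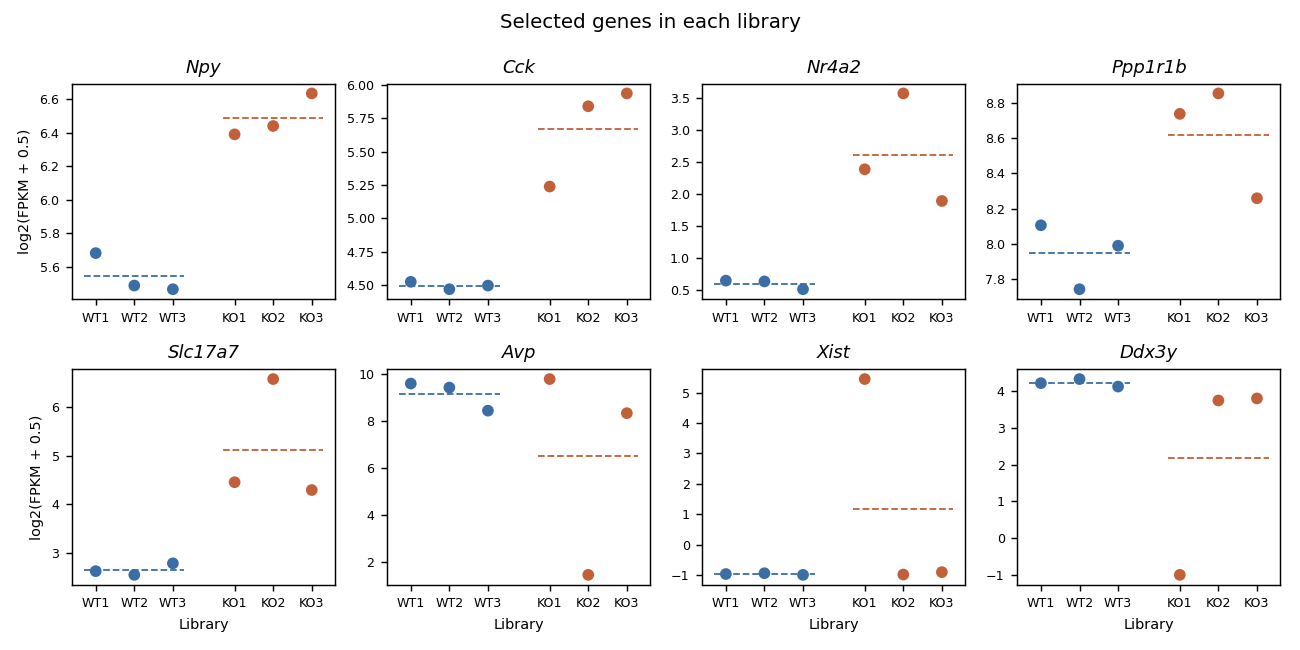
Level of 8 genes as log2(FPKM + 0.5) (vertical axes, each with its own scale) in each of the 6 libraries (horizontal axes), with dashed lines for the group means. Slc17a7 and Avp differ most in KO replicate 2, at 94.3 and 2.20 FPKM, and Xist and Ddx3y in KO replicate 1.

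Immediate early genes, which neurons switch on with activity, were higher in KO as a list. Over 36 genes the median log2 difference was 0.36, and 13 were higher and 0 lower when adjusted over the list alone (camera adjusted p = 2.92e-09, adjusted p = 0.574 with an estimated correlation). Junb measured 13.1 ± 1.57 FPKM in WT and 20.5 ± 2.63 in KO. Nr4a2, also a marker of some cortical neurons, was 1.02 ± 0.0766 in WT and 4.73, 11.4 and 3.21 FPKM in KO replicates 1 to 3. Nptx2 (log2 0.59 ± 0.13) and the clock gene Per1 (0.41 ± 0.08) were also among the 13. The list median was 0.32 without KO replicate 2. Excitatory neuron markers were higher in KO too, and whether activity or a different mix of cells moved the immediate early genes was not tested. Per1 was counted as well in the circadian clock list, whose 19 genes had a median of 0.23 with 4 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000580, adjusted p = 0.574 with an estimated correlation). Npas2 (0.70 ± 0.14), Bhlhe40 (0.49 ± 0.12) and Ciart (0.49 ± 0.12) made up the rest of the 4.

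Oligodendrocyte and myelin genes were lower in KO as a list. Over 26 genes the median log2 difference was -0.51, with 16 lower and 0 higher when adjusted over the list alone (camera adjusted p = 4.67e-12, adjusted p = 0.574 with an estimated correlation). Opalin (-1.07 ± 0.17), Ermn (-0.72 ± 0.14), Gal3st1 (-0.51 ± 0.10) and Aspa (-0.67 ± 0.13) were among the 16, whereas Mbp, a major myelin protein gene, measured 478 ± 84.5 FPKM in WT and 436 ± 105 in KO. The mean log2 level of the list was 5.07, 5.43 and 5.22 in WT replicates 1 to 3 and 4.83, 4.43 and 4.94 in KO replicates 1 to 3. KO replicate 2 was lowest, a median log2 of -0.45 from the mean of the other 2 KO libraries (random lists -0.09 to 0.10, again too narrow for a test). Without that library the KO minus WT median was -0.42. Oligodendrocyte precursor genes had a median of -0.18 over 16 genes and 0 members adjusted over the list alone (camera adjusted p = 0.00347, adjusted p = 0.574 with an estimated correlation). Gpr17 (-0.49) and Enpp6 (-0.49) had the smallest p, and the call was lost without KO replicate 2 (median -0.11, adjusted p = 0.0530). Microglial genes had a median of -0.19 over 27 genes, with 1 lower and 0 higher adjusted over the list alone, Fcrls at 10.7 ± 1.82 and 5.77 ± 0.977 FPKM (camera adjusted p = 0.00196, adjusted p = 0.574 with an estimated correlation). Siglech (-0.37) and Olfml3 (-0.57) had the next smallest p. Astrocyte genes did not pass (25 genes, median -0.06, adjusted p = 0.0900).

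Stress hormone and neuropeptide genes were higher in KO as a list. Over 30 genes the median log2 difference was 0.14, with 6 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00950, adjusted p = 0.574 with an estimated correlation). The 6 were Npy, Cck, its receptor gene Cckbr (2.15 ± 0.0522 and 5.54 ± 1.68 FPKM), Per1, the corticotropin-releasing hormone binding protein gene Crhbp (2.27 ± 0.457 and 4.95 ± 1.37 FPKM) and Fkbp5. The 1 lower gene was Crh, at 8.51 ± 0.721 and 5.68 ± 1.10 FPKM. The call was lost among genes of at least 5 FPKM (median 0.08), and the median was 0.09 without WT replicate 3 and 0.09 after rescaling to an equal sum. Without KO replicate 1, Cck (log2 1.39, adjusted p = 0.00612) and Cckbr (1.40, adjusted p = 0.0127) were among 9 genes that passed over all genes.

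GABAergic interneuron genes did not pass as a list (32 genes, adjusted p = 0.623). Their median log2 difference was -0.02 while their mean was 0.08 and the test direction higher, so the signs differ. Adjusted over the list alone 3 were higher and 0 lower, namely Npy, Cck and Crhbp, which the neuropeptide list shares. Tac1 measured 51.1 ± 9.19 and 71.3 ± 9.56 FPKM. GABA receptor genes did not pass either (19 genes, median -0.03, adjusted p = 0.442), with 3 lower and 0 higher adjusted over the list alone. Among the 3 was the receptor subunit gene Gabrb2 (28.0 ± 3.77 FPKM in WT and 19.9 ± 2.28 in KO), and Gabrg1 had a log2 difference of -0.54. Glutamate receptor genes had a median of 0.08 over 22 genes and 0 members adjusted over the list alone (adjusted p = 0.604). Gria4 (-0.35), Grik3 (0.31), Grik5 (0.32) and Grin2d (-0.38) had the smallest p.

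Synaptic and channel genes had small positive medians. Postsynaptic scaffold and plasticity genes had a median log2 difference of 0.23 over 29 genes (camera adjusted p = 0.000121, adjusted p = 0.608 with an estimated correlation). Camk2a (0.73 ± 0.18) and Dlg3 (0.40 ± 0.11) were among the genes with the smallest p, and Camk2a is also in the excitatory list. The median was 0.13 without KO replicate 2, 0.14 without WT replicate 2 and 0.14 with array quality weights. Presynaptic vesicle genes had a median of 0.21 over 30 genes (camera adjusted p = 0.00347, adjusted p = 0.608 with an estimated correlation), with Vamp2 at 0.39 ± 0.09 and Cplx3 at 0.92 ± 0.20. That median was 0.13 without KO replicate 2, and the call was lost under quantile normalization (0.11). Calcium and sodium channel genes had a median of 0.17 over 25 genes (camera adjusted p = 0.00405, adjusted p = 0.708 with an estimated correlation), with Cacnb3 at 0.64 ± 0.17. The channel call was lost without WT replicate 3 (0.14) or KO replicate 2 (0.06), among genes of at least 5 FPKM (0.14) and with array quality weights (0.09), and the median was 0.11 without WT replicate 2 and 0.11 after rescaling to an equal sum. Each of these 3 lists had 0 members adjusted over the list alone. The Cntnap and contactin family, relatives and partners of Cntnap4, was lower (12 genes, median -0.14, camera adjusted p = 0.00963, adjusted p = 0.574 with an estimated correlation). Adjusted over the list alone 2 were lower and 0 higher, Cntn2 (-0.35 ± 0.08) and Cntnap5c (-0.54 ± 0.14). That call was lost without WT replicate 1 (adjusted p = 0.0616) or KO replicate 1 (adjusted p = 0.134), and the median was -0.22 after rescaling to an equal sum.

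Blood genes were higher in KO, with a median log2 difference of 0.99 over 10 genes (camera adjusted p = 1.42e-05, adjusted p = 0.574 with an estimated correlation). Adjusted over the list alone 6 were higher and 0 lower. They include the neutrophil gene S100a8 (2.38 ± 0.391 FPKM in WT and 9.46 ± 5.37 in KO) and the haemoglobin gene Hbb-bs (21.5 ± 1.06 and 36.3 ± 11.3). Haemoglobin genes have close copies and are uncertain. With no filter on low values the median was 0.64. Genes of nuclear-encoded oxidative phosphorylation (75 genes, median 0.11, camera adjusted p = 0.00374, adjusted p = 0.702 with an estimated correlation) and cytosolic ribosomal proteins (78 genes, median 0.11, camera adjusted p = 0.00796, adjusted p = 0.802 with an estimated correlation) had 0 members adjusted over the list alone. Atp5k (0.97 ± 0.19) and Rps29 (1.37 ± 0.33) had the smallest p in each, and processed copies of such genes make single values uncertain. Without KO replicate 1 both calls were lost, with medians of 0.09 and 0.03, as they were under quantile normalization (0.03 each). Rescaling to an equal sum kept both calls with medians of 0.06 and 0.05. The ribosomal call was lost too among genes of at least 5 FPKM (0.11). The ribosomal call was also lost without WT replicate 1 (0.10), WT replicate 3 (0.07) or KO replicate 3 (0.09), and its median was 0.17 without WT replicate 2 and 0.21 without KO replicate 2. Cholesterol synthesis genes had a median of 0.15 over 22 genes (camera adjusted p = 0.0315, adjusted p = 0.702 with an estimated correlation), and Fdft1 (0.41 ± 0.08) was the 1 higher gene adjusted over the list alone, with 0 lower. That call was lost without WT replicate 2 (0.14), WT replicate 3 (0.11), KO replicate 2 (0.07) or KO replicate 3 (0.16), and with the 5 FPKM filter (0.14), rescaling to an equal sum (0.09) or quantile normalization (0.14). With array quality weights it held at 0.10. Transcripts that track RNA quality and polyadenylation had a median of -0.22 over 11 genes and 0 members adjusted over the list alone (camera adjusted p = 0.0382, adjusted p = 0.574 with an estimated correlation). Malat1, an abundant nuclear RNA, measured 121 ± 8.81 FPKM in WT and 98.2 ± 13.9 in KO, and the call was lost without WT replicate 2 (-0.16), KO replicate 1 (-0.20) or KO replicate 2 (-0.27), and with no filter (-0.20) or the 5 FPKM filter (-0.04).

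**Figure D3:**
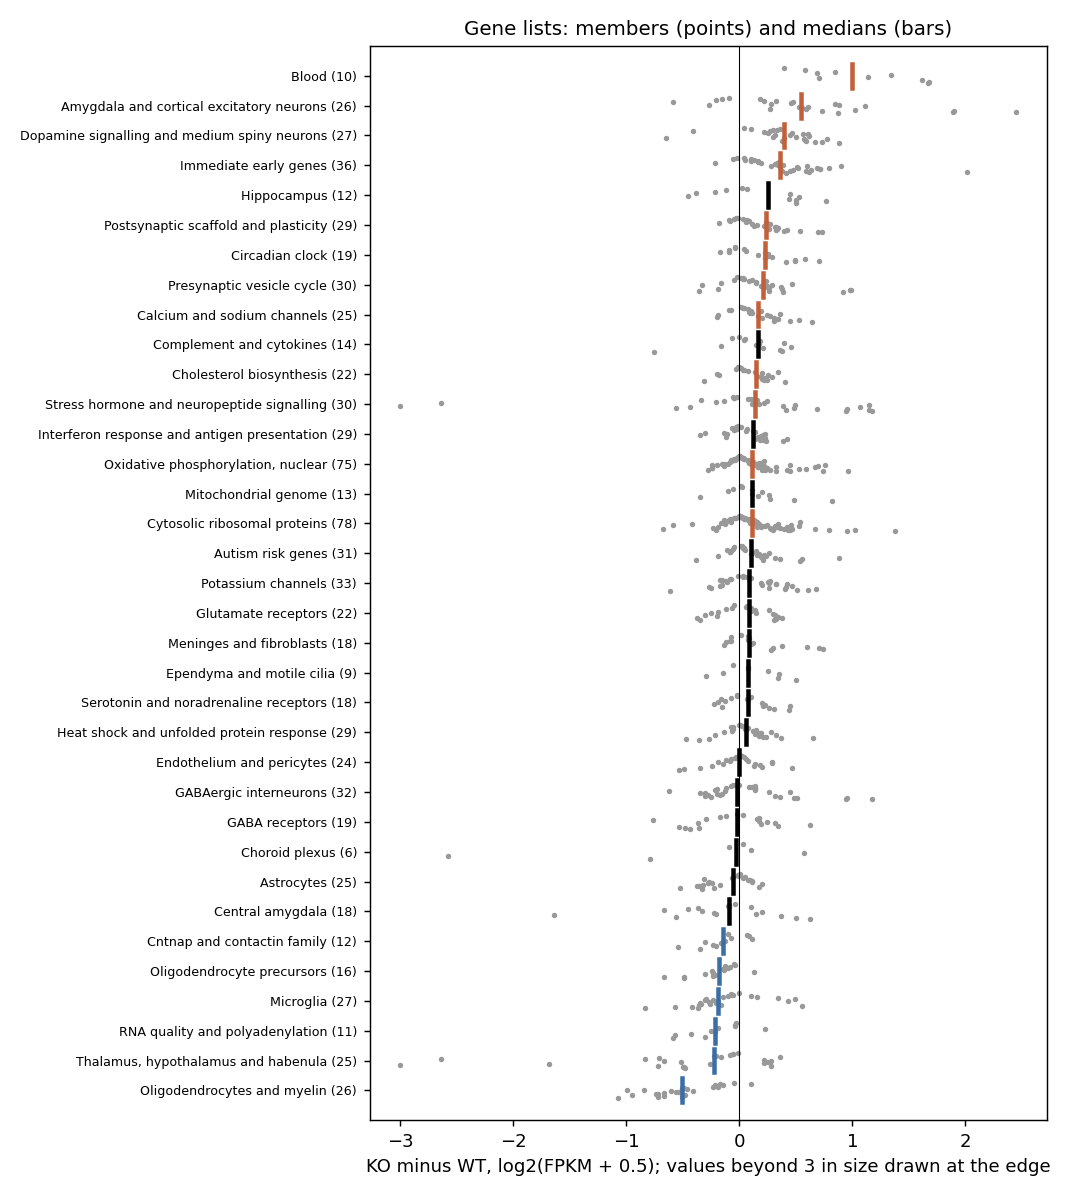
Log2 difference (KO minus WT, horizontal axis) of each tested member (points) and the median (bars) of the 35 gene lists (vertical axis, number of tested genes in parentheses). Orange bars mark the 12 lists higher and blue bars the 6 lists lower at the preset correlation, none of which passed with an estimated correlation, and medians run from -0.51 for oligodendrocyte genes to 0.99 for blood genes.

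The remaining lists did not pass. Hippocampal genes had a median log2 difference of 0.25 over 12 genes (adjusted p = 0.0964), with 5 higher and 0 lower adjusted over the list alone, among them Wfs1 and Dkk3. Central amygdala genes had a median of -0.09 over 18 genes (adjusted p = 0.696), with Ezr, Wfs1 and Pmepa1 higher and Crh lower adjusted over the list alone. Potassium channel genes had a median of 0.09 over 33 genes (adjusted p = 0.231), with Kcnj3 higher and Kcnj10 lower adjusted over the list alone. Choroid plexus genes (6 genes, median -0.03, adjusted p = 0.232) held Enpp2, lower adjusted over the list alone, and Ttr, at 26.9, 29.6 and 24.8 FPKM in WT and 4.01, 0.634 and 18.7 FPKM in KO replicates 1 to 3. Endothelial and pericyte genes (24 genes, median -0.002, adjusted p = 0.559) had Mcam and Itm2a lower, and complement and cytokine genes (14 genes, median 0.16, adjusted p = 0.571) had Il33 lower, adjusted over the list alone. Autism risk genes (31 genes, median 0.10, adjusted p = 0.0537), meningeal genes (18 genes, 0.08, adjusted p = 0.275) and interferon genes (29 genes, 0.12, adjusted p = 0.308) had 0 members adjusted over the list alone. So did heat shock genes (29 genes, 0.06, adjusted p = 0.339), serotonin and noradrenaline receptors (18 genes, 0.07, adjusted p = 0.427), ependymal genes (9 genes, 0.08, adjusted p = 0.442) and the mitochondrial genome (13 genes, 0.11, adjusted p = 0.662), as did astrocyte genes.

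Genes around Cntnap4 on chromosome 8 were examined because a knockout allele can carry flanking DNA of another strain. Within 10 Mb, 0 of 200 tested genes passed the adjusted threshold, against 2 of 15954 elsewhere (Fisher's exact p = 1). An unadjusted limma p under 0.05 was reached by 27 of the 200 (13.5%) and by 15.2% of genes elsewhere (Fisher's exact p = 0.553). Zfp1, a zinc finger gene less than 1 Mb from Cntnap4, measured 8.90 ± 0.413 FPKM in WT and 11.6 ± 0.851 in KO (adjusted p = 0.200). Zfp1 was chosen after its values were seen.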

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

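Voom for Cntnap4 and the lists, the 10-read filter and the removal of the length trend were chosen after seeing the data. The count of changed genes, 2 as reported, was 0 with a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, protein-coding genes, voom on recovered reads, at least 10 reads per library or the replicate block, was 1 under quantile normalization and was 8 after rescaling to an equal FPKM sum, with 1 higher. Leaving out 1 library gave 0 to 9 genes. The count of lists, 18 as reported, was 0 with an estimated correlation and 0 by fry, and 14 to 19 under the other alternatives, including 14 to 19 without 1 library. The block left it at 18. The replicate numbers showed no sign of pairing the samples: correlations of deviations for equal numbers were -0.0899, -0.138 and -0.0661, and no sample correlated best with its own number. Deviations of 3 samples from their group mean sum to 0 in each gene, so these correlations constrain each other. This check therefore could not exclude a weak pairing. Cntnap4 ranged from -0.80 to -1.35 without passing in any fit that tested it, and was not testable at a mean of 5 FPKM. Near Cntnap4, 0 genes passed throughout, a count that could hardly differ when so few genes pass anywhere. The test direction of GABAergic interneurons reversed with a mean FPKM of at least 5 (median -0.0686) and without KO replicate 3 (-0.0413; -0.0413 to 0.0373 without 1 library), and that of Glutamate receptors without WT replicate 3 (-0.0216; -0.0216 to 0.154) and KO replicate 2 (0.0309). The limits to protein-coding genes, to at least 5 FPKM and to at least 10 reads per library left both called genes out of the test. Those counts therefore could not include them. For the other changed counts and the reversals the cause was not tested. Among 1732 fits of 98 other named genes, 1719 kept direction and side of the threshold, 8 lost the threshold, 5 passed it and 0 reversed. Of these genes only Scarna17 passed as reported, so keeping the same side mostly meant still not passing. They were also picked for small p, so a reversal was unlikely and this tally does not measure stability. The median shift of all genes was 0.01 as deposited and -0.05 after rescaling. Depth limits short genes: 3 reads on a gene of 1 kilobase correspond to 0.138 to 0.169 FPKM.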

Other observations

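Apart from the tests on other splits of the samples, every test in this part was chosen after the result it concerns had been seen. The fit without KO replicate 2 was itself planned, and only its use here to weigh an explanation came after. Genes of cholinergic neurons, which use acetylcholine, lay lower in KO. Chat, the acetylcholine-synthesizing enzyme, measured 13.2 ± 0.511 FPKM in WT and 8.54 ± 2.21 in KO, Slc18a3 11.1 ± 0.743 and 6.70 ± 1.15 FPKM, and Ngfr 22.0 ± 2.01 and 10.3 ± 4.76 FPKM. A list of 12 such genes, put together after seeing that some of them were lower, had a median log2 difference of -0.47, with 11 of 12 negative. Its camera p was 3.59e-07 at the preset correlation and 0.101 with an estimated correlation. Because its genes were picked for the pattern, that p does not test it, and an explanation by fewer cholinergic cells, at first counted as met by this list, was set aside for that reason.

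The ribosomal protein gene Rps3a1 and its copies differed among KO libraries. Rps3a2, Rps3a3 and Gm6166 together took 39.8% and 37.5% of the summed reads of the family in KO replicates 2 and 3, and 0.779% to 0.902% in the other 4 libraries. Rps3a1 itself measured 205 and 242 FPKM in those 2 libraries and 382 to 508 FPKM elsewhere. Such copies share reads, and these values are uncertain. KO replicate 1 lay with the WT libraries here. It is also the library with Xist, and the KO library nearest to WT for Cntnap4. What set KO replicates 2 and 3 apart for this family was not tested. Across 12201 protein-coding genes, which are not independent replicates, the log2 difference and gene length had a Spearman correlation of -0.118. In WT replicate 1, 6 genes stood apart from the other libraries, all lower, among them Slc13a4 (0.419 FPKM against 2.90 to 4.05) and Aldh1a2, both expressed in meninges.

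The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2 genes and the highest of the others also 2, and 2 of the 10 splits gave as many as the real one. For lists the real split gave 18 and the highest other 21, and 4 of the 10 splits gave as many. The split with 21 set WT replicate 1 with KO replicates 2 and 3 against the rest. Genes with an unadjusted p under 0.05 numbered 2457 in the real split and at most 841 in the others. Every other split mixes WT and KO libraries, so any difference between WT and KO, also one of sex or dissection, adds to its spread. The counts of the other splits therefore do not give the level of chance, and the contrast with them does not single out genotype.

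The library labelled KO replicate 1 had Xist at 43.0 FPKM and 0 Y-linked reads. A library made from a female animal is a candidate explanation: 4 of 4 genes known to escape X inactivation measured 1.13 to 1.64 times the mean of the other 5 libraries, in line with it. A mixture of male and female tissue is argued against, since a count of 0 allows Y-linked reads at no more than 0.0874% of the mean of the other libraries. Whether a mouse of the other sex was taken or a sample exchanged with one from outside these 6 stays open. Sex then differs within KO and is unbalanced between the groups, as every WT library had Y-linked reads. It could add to the spread in KO and also shift KO minus WT differences. If a sample was exchanged, the KO label of that library would be in doubt too, in every comparison that uses it.

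Excitatory and hypothalamic genes varied among libraries of 1 genotype. A different mix of brain regions in the dissected pieces is a candidate explanation. KO replicate 2 exceeded the mean of KO replicates 1 and 3 by a median log2 of 0.61 over the excitatory list. The middle 95% of 10000 random lists matched on level spans -0.10 to 0.12. In KO replicate 2 the dopamine and medium spiny list lay at 0.51 (random -0.11 to 0.09), the hypothalamic list at -0.29 (random -0.14 to 0.11) and the oligodendrocyte list at -0.45 (random -0.09 to 0.10). In that library 27 genes stood apart, Avp, Otp and Sim1 among them. It was singled out after its excitatory and hypothalamic genes were seen, so these values restate that observation and cannot decide between causes. Random lists also lack the correlation between genes of a cell-type list, so their range is too narrow for a test. Genotype alone is argued against for Avp and Oxt, since the highest KO library exceeded the lowest 406-fold for Avp, against 2.24-fold within WT. For the excitatory genes it cannot be told apart from dissection: the list median stayed at 0.32 without KO replicate 2, and Slc17a7 was above every WT library in all 3 KO libraries.

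Oligodendrocyte genes were lower in KO. A gene length trend as the whole cause is argued against, because the list median was -0.53 with the trend removed. A lower share of oligodendrocytes, which could lower their genes by 1 common factor, stays open: 0 of 26 members departed from the list mean after adjustment (lowest adjusted p = 0.0976), which met the criterion first written, but 8 had an unadjusted limma p under 0.05, and a condition on that count was added after the result was seen. Less white matter in the KO pieces, as part of a different regional mix, cannot be told apart from the genotype, as the KO minus WT difference of the list mean was -0.50 on the log2 scale, with every KO library below every WT library. No measurement here separates cell number from expression per cell.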
